A study of Drosophila melanogaster with 6 samples.

How the data were processed

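Poly-A transcripts were counted in 6 libraries of Drosophila melanogaster intestinal progenitor cells, 3 labelled control (wild-type) and 3 labelled Pex5-depleted. Per the labels' protocols, each replicate came from 200 dissected guts whose midguts were dissociated with elastase, and about 40000 GFP-positive cells were sorted by flow cytometry with propidium iodide added before the sort. The gate was set with flies carrying the esg-driven GFP and with flies lacking GFP. RNA was purified from the sorted cells and made into libraries with the QIAseq UPX 3' transcriptome kit, which tags each captured molecule near its 3' end with a well index and a unique molecular identifier (UMI). A UMI lets copies made by PCR be counted once, so a count stands for captured molecules. The labels do not say how Pex5 was depleted or give the sex and age of the flies. The labels call the replicates biological, and nothing in them ties control replicate 1 to Pex5-depleted replicate 1.

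The authors deposited a table of UMI counts per gene and well index. Per the deposited run metrics, which cover the whole run and not these 6 libraries alone, the run held 481949149 reads. Of these, 33.4% were dropped because the well index matched no oligo within a Hamming distance of 1, 6.41% because they were under 25 bp, 5.83% because they did not map, 5.04% because they fell outside the annotation and 0.717% because they mapped to several loci. The remaining 48.6% gave 20797773 UMIs, a mean of 11.3 reads per UMI. The submitters' processing notes name HISAT2, StringTie, DESeq2 and genome build dm6 without roles or versions. Reads mapping to several loci were dropped, so transcripts of near-identical genes, such as the lysozyme cluster and the Hsp70 copies, are undercounted to an unknown degree, and their values are uncertain. The sources used here do not say whether the counting used strand.

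The UMI table has 29 further columns of other well indexes that match no sample here, and these were not used. The 6 spike-in rows that name no Drosophila gene held 7 UMIs in the 6 libraries (3.37e-05% of the total) and were left out. Totals per library differed from the UMIs of the deposited metrics only by these spike-in UMIs. Depth was 3539552, 3013033 and 3547768 UMIs in control replicates 1, 2 and 3, and 2573882, 4793433 and 3324594 UMIs in the replicates labelled Pex5-depleted 1, 2 and 3. A count of 0 in a single library allows up to 3 UMIs, which is between 0.626 and 1.17 CPM. Such floors cover counting error only. Pairs of replicates within a group differed by more than sampling noise (chi-square per degree of freedom between 10.3 and 16.3), so none was treated as a repeat deposit.

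The authors also deposited a table of fold changes, in which the fold is a signed linear score with no value between -1 and 1, with p-values and false discovery rates. Per the file headers, the table does not name the sides of its comparison, and its tool is not given in the file. It was read only beside the counts and entered no test of genes.

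Gene positions are those of the UMI table. Of its 13189 genes, each with at least 1 UMI in the 6 libraries, 13087 were in Ensembl release 115 of the BDGP6 annotation, and 13009 had the same start and end there. Transcript lengths, the longest per gene, came from that annotation and covered 99.1% of the tested genes.

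The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the UMI counts as deposited, with TMM factors, edgeR's expression filter with its minimum count of 10, no covariate, and Benjamini-Hochberg adjustment over all tested genes with a threshold of 0.05. All fold changes give the libraries labelled Pex5-depleted over control. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are UMI counts scaled by library size and TMM factor and are given as mean ± SD with n = 3. A fold against a group at 0 was taken against 3 counts over the whole group.

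In data simulated from the real means and library sizes over 5639 genes, with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 27% of the 2-fold and 60% of the 4-fold changes. Above a log2 CPM of 5 it recovered 62.5% and 100%, and 5 of its calls were false.

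Before the data were examined, 23 gene lists were fixed: 15 of pathways and 8 of cell type markers. The 19 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. A count given as adjusted over the list alone uses the p-values of that list's members only. In simulated data camera found a planted list of 20 genes shifted by 0.60 on the log2 scale, with an adjusted p of 1.62e-10, and called 0 of 20 unshifted lists. Camera with an estimated correlation and fry found the same planted list, with adjusted p of 0.0359 and 0.0107, and also called 0 of 20. The simulated genes were drawn independently of each other, so these runs could not show false calls that arise from correlated genes. In the real data the heat shock, enterocyte and enteroendocrine lists had estimated correlations of 0.415, 0.198 and 0.193.

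The rule for named genes was also fixed before the data were examined. It names Pex5 and ERp60, then the 12 largest and 12 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, then up to 3 members of each list past the threshold by smallest p, or the member with the smallest p where none passed. This gave 51 genes. All other genes named, such as esg, NPF, Hsp70Aa and Pex13, were chosen after their values were seen.

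Alternatives fixed before the data were examined were median-of-ratios (RLE) factors, no composition factor, no count filter, a filter of at least 10 UMIs in at least 3 libraries, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, camera with an estimated correlation and the rotation test fry. An offset for a trend with transcript length per library was added after the data were seen, because the trend differed between libraries (Spearman rho across genes between -0.146 and 0.332). On simulated data the offset took a planted rho of 0.278 to 0.0078.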

Results

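The data are transcript counts of intestinal progenitor cells, the stem cells and their undifferentiated daughters that renew the fly midgut epithelium. The cells were sorted for GFP expressed under escargot (esg), a transcription factor gene active in these progenitors. There were 3 control libraries and 3 libraries labelled Pex5-depleted, with 2573882 to 4793433 UMIs and 8890 to 10349 detected genes each. Cytosolic ribosomal protein transcripts took 52.9% to 56.4% of the UMIs. Transcripts encoded in the mitochondrial genome took 5.84%, 7.44% and 5.63% in control replicates 1, 2 and 3, and 8.88%, 8.05% and 9.31% in the replicates labelled Pex5-depleted. Heat shock transcripts took 1.53%, 2.42% and 3.30% in the controls and 3.45%, 4.07% and 3.68% in the other group. On the first principal component, which held 30.1% of the variance, the controls lay between -31.2 and -21.1 and the other libraries between 14.2 and 39.5.

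The series concerns the disulfide isomerase ERp60 and ether phospholipids in the gut epithelium, and its only comparison is of Pex5-depleted with control progenitors. Pex5 encodes the receptor that carries enzymes into peroxisomes, the organelles where ether lipid synthesis begins. The Pex5 transcript (FBgn0023516, chromosome X, 1866832 to 1869061, minus strand) was counted 8, 6 and 14 times in the control libraries and 2, 21 and 41 times in the libraries labelled Pex5-depleted. That is 2.65 ± 0.943 CPM against 6.38 ± 6.86 CPM (SD, n = 3 each). The log2 fold change was 1.25 (SE 0.87, 95% interval -0.62 to 3.11), and edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.607. The fitted direction thus ran against the label without passing the test, and without the replicates labelled Pex5-depleted 3 and 1 in turn the log2 fold change was -0.03 and 1.76. For this reason the group is called by its label throughout, and every direction below rests on that label.

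ERp60 (FBgn0033663, chromosome 2R, 11887568 to 11890979, minus strand), which forms and rearranges disulfide bonds in the endoplasmic reticulum, stood at 207 ± 26.9 CPM in the controls and 209 ± 15.0 CPM in the libraries labelled Pex5-depleted (SD, n = 3 each). Its log2 fold change was 0.01 (SE 0.18, 95% interval -0.36 to 0.38), with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.991, and the sign turned with RLE factors (-0.01) and with no composition factor (-0.05). With all 6 libraries the interval thus reached no further than 0.38 on the log2 scale in either direction. In the fits without 1 library the log2 fold change lay between -0.075 and 0.112. The SE was 0.196 without control replicate 1 and 0.209 without control replicate 2, so a larger change is less firmly excluded there. The esg transcript itself, the basis of the sort, was 42.5 ± 13.0 CPM in the controls and 55.4 ± 9.60 CPM in the other group (adjusted p = 0.615 by edgeR, Benjamini-Hochberg).

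**Figure D1:**
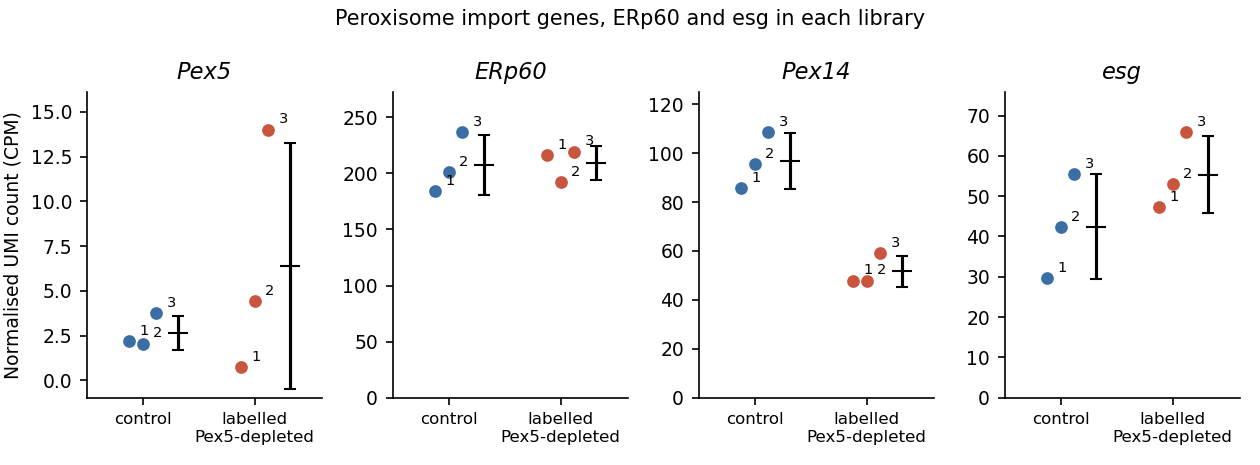
Normalised UMI counts (CPM, vertical axes) of Pex5, ERp60, Pex14 and esg in each of the 3 control libraries (blue) and 3 libraries labelled Pex5-depleted (red), with replicate numbers beside the points; the black marks are the mean and SD of each group. Pex5 is at 2.17, 2.05 and 3.74 CPM in the controls and at 0.726, 4.41 and 14.01 CPM in the other group, while ERp60 lies near 208 CPM in both.

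Gut lysozyme genes were among those that rose most in the libraries labelled Pex5-depleted, with a cytochrome P450 gene, a digestive protease gene and a metallothionein gene. Genes of a septate junction tetraspanin, of immune deficiency pathway members, of a basement membrane proteoglycan and of a copper chaperone fell. Among the fixed lists, camera with its preset correlation called enteroendocrine genes lower and heat shock and enterocyte genes higher. None of these 3 calls held with an estimated correlation (adjusted p = 0.395 for each) or with fry (adjusted p = 0.0984, 0.145 and 0.259, Benjamini-Hochberg). In all, 47 of 5639 tested genes were higher and 46 were lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Of these 93 genes, 92 had groups that did not overlap, as had 19.2% of all tested genes, where chance gives 10%. A further measure is the 745 genes at an unadjusted p under 0.05, where 282 are expected by chance. Each fit without 1 library called fewer genes: 17 without control replicate 1, 80 without control replicate 2, 44 without control replicate 3, and 34, 32 and 28 without the replicates labelled Pex5-depleted 1, 2 and 3. In all 6 of those fits 13 of the 93 calls held, among them LysB, LysC, LysD, LysE, Cyp4p2, Hsp83, PGRP-LB and CG2065. Another 22 of the 93 calls held in none of the 6 fits.

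Of the genes that rose, 4 were neighbouring lysozyme genes on chromosome 3L, which encode bacteria-degrading enzymes secreted in the gut. LysB (1207371 to 1207981) went from 0.996 ± 0.632 to 41.0 ± 20.2 CPM and LysD (1210717 to 1211196) from 5.25 ± 2.02 to 104 ± 65.2 CPM (SD, n = 3 each). Their log2 fold changes were 5.34 (SE 0.57) and 4.27 (SE 0.44), and both had an adjusted p of 0.000295 (edgeR quasi-likelihood, Benjamini-Hochberg). LysC and LysE had log2 fold changes of 5.37 and 4.28. These genes are near-identical copies, LysC (1210485 to 1210726) overlaps LysD, and their separate values are uncertain. The serine protease gene Jon25Biii rose by 3.33 on the log2 scale (SE 0.56), from 19.5 ± 18.9 to 193 ± 131 CPM. The P450 gene Cyp4p2 rose by 3.65 (SE 0.42), from 8.18 ± 6.10 to 105 ± 34.5 CPM, and the metallothionein gene MtnA, whose product binds metal ions, rose by 2.18 (SE 0.49). CG17633 had no UMI in the 3 controls and 14, 31 and 77 in the other libraries, which is at least 38.4-fold higher against a floor of 3 counts over the control group. The remaining genes named by the rule were CG16749, CG32581, CG15629 and CG3301, with log2 fold changes of 4.59, 3.71, 2.63 and 2.21. CG16749 had 1, 2 and 1 control UMIs and CG32581 had 4, 0 and 4. Of the genes named here as risen, the lysozyme genes and Cyp4p2 kept their call in each of the 6 fits without 1 library. CG32581 passed in 0 of those fits, MtnA and CG15629 in 1, and CG3301 in 2. Jon25Biii, CG17633 and CG16749 passed in 4. Where calls were lost, the adjusted p went up to 0.203 (edgeR quasi-likelihood, Benjamini-Hochberg). With limma-voom the calls of LysB, LysC and LysE ended (adjusted p = 0.0580, 0.0825 and 0.128), as did those of CG17633, CG16749, CG32581, CG3301 and MtnA (up to 0.241), while LysD and Cyp4p2 kept theirs.

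Among the genes that fell, Tsp2A, a tetraspanin of the smooth septate junctions that seal the gut epithelium, went from 41.0 ± 3.51 to 10.8 ± 4.47 CPM (SD, n = 3 each), a log2 fold change of -1.94 (SE 0.36). PGRP-LB encodes an enzyme that cuts bacterial peptidoglycan and dampens the immune deficiency (Imd) pathway. It went from 75.6 ± 12.2 to 23.7 ± 3.77 CPM, a log2 fold change of -1.68 (SE 0.26, adjusted p = 0.00476 by edgeR quasi-likelihood, Benjamini-Hochberg). AttD, an attacin antimicrobial peptide gene, had a log2 fold change of -1.77 (SE 0.42). The perlecan gene trol, a basement membrane proteoglycan, fell by 1.50 (SE 0.31), the copper chaperone gene Atox1 fell by 1.48 (SE 0.31), and Oscillin, a glucosamine-6-phosphate deaminase gene, fell by 2.72 (SE 0.56). CG42807, CG31436, CG6218, CG42565, CG5910 and CG2065 had log2 fold changes of -2.72, -2.19, -1.90, -1.87, -1.66 and -1.66. PGRP-LB and CG2065 kept their call in each of the 6 fits without 1 library. CG31436, CG6218, CG42565 and AttD passed in 0 of those fits, trol and Atox1 in 1, and Oscillin in 2. Tsp2A and CG42807 passed in 3 and CG5910 in 4. Where calls were lost, the adjusted p went up to 0.206 (edgeR quasi-likelihood, Benjamini-Hochberg). With limma-voom the calls of Oscillin, CG31436, CG42565 and AttD ended, with adjusted p up to 0.128, and with the length offset those of CG31436 and AttD did (0.0506 and 0.0575).

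**Figure D2:**
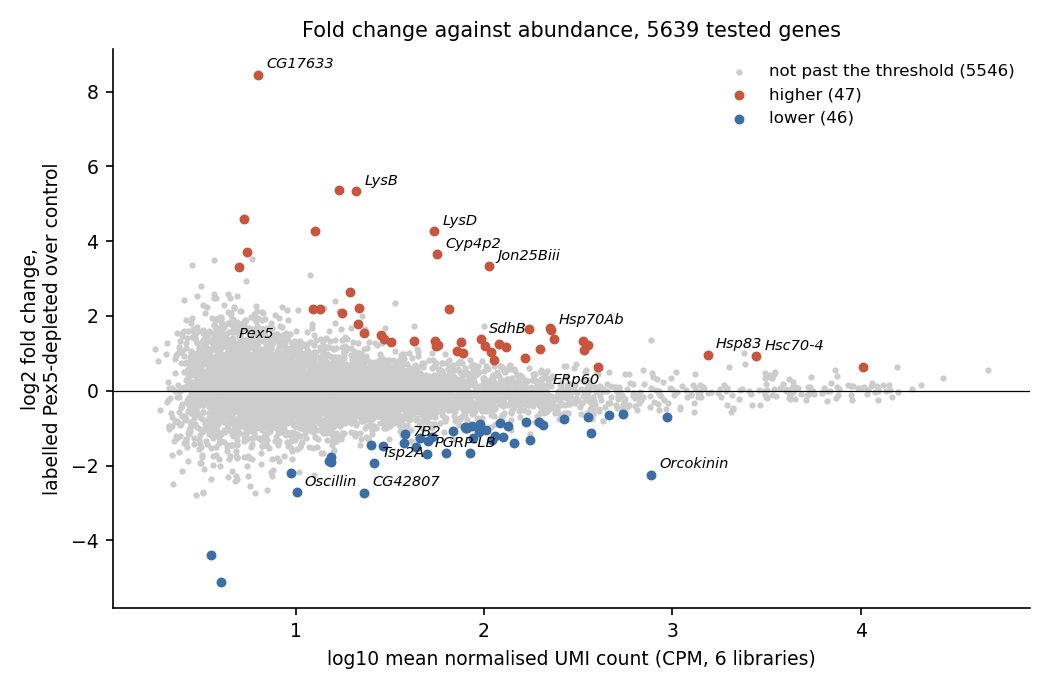
Log2 fold change of the libraries labelled Pex5-depleted over control (vertical axis) against the log10 mean CPM of the 6 libraries (horizontal axis) for each of 5639 tested genes; coloured points passed an adjusted p of 0.05. The 47 higher genes (red) reach log2 fold changes of 8.45, a fitted value for CG17633 with no control UMI, and the 46 lower genes (blue) reach -5.12; Pex5 and ERp60 are grey.

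Enteroendocrine cells are the hormone-secreting cells of the gut epithelium, and their markers were among the lists of other cell types the sort could hold. Of 27 markers 18 were tested, 3 fell, 0 rose and 15 did not pass, and 17 of the 18 fold changes were negative with a median log2 fold change of -1.14. Adjusted over the list alone, 11 were lower. The 3 were 7B2, a chaperone of a prohormone convertase (54.7 ± 12.3 to 20.9 ± 2.76 CPM, log2 fold change -1.39, SE 0.28), Phm, an enzyme that amidates neuropeptides (139 ± 16.4 to 66.6 ± 20.7 CPM, -1.06, SE 0.24), and the neuropeptide gene Orcokinin (1278 ± 978 to 270 ± 83.8 CPM, -2.24, SE 0.51; SD, n = 3 each). The Orcokinin groups overlapped, with 2175, 1424 and 234 CPM in the controls. Its adjusted p of 0.0417 by edgeR rose to 0.0936 with DESeq2 and 0.117 with limma-voom (Benjamini-Hochberg in each). Abundant members that did not pass were NPF, at 545 ± 122 against 312 ± 80.5 CPM, and Tk, at 93.3 ± 24.7 against 55.6 ± 6.59 CPM. The camera test gave the list an adjusted p of 2.59e-08 (Benjamini-Hochberg). The adjusted p was 0.395 with an estimated correlation and 0.0984 with fry, so the call held with neither. The calls of 7B2, Phm and Orcokinin were each lost in 4 or more of the 6 edgeR fits without 1 library, with adjusted p up to 0.106, 0.177 and 0.227.

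The list of heat shock and dissociation stress genes was higher, with 18 of 20 genes tested, 5 risen, 0 fallen, 13 not past the threshold and a median log2 fold change of 0.82. Adjusted over the list alone, 12 were higher. Hsp83, the fly Hsp90, went from 1044 ± 103 to 2041 ± 49.5 CPM (log2 fold change 0.97, SE 0.14) and the constitutive chaperone gene Hsc70-4 from 1923 ± 422 to 3663 ± 129 CPM (0.93, SE 0.16; SD, n = 3 each). Hsp70Ab, Hsp70Aa and Hsp70Bc, near-identical heat-inducible copies whose separate values are uncertain, rose by 1.63, 1.69 and 1.34 on the log2 scale. The most abundant small heat shock gene, Hsp26, did not pass, at 12350 ± 4802 against 19060 ± 3000 CPM. The camera adjusted p was 3.72e-06 (Benjamini-Hochberg). It was 0.395 with an estimated correlation and 0.145 with fry. In edgeR fits without 1 library, Hsc70-4 lost its call without control replicate 1 or the replicate labelled Pex5-depleted 2 (adjusted p up to 0.0530), and Hsp70Ab without the replicates labelled Pex5-depleted 2 or 3 (up to 0.0665). Hsp70Aa passed in 3 and Hsp70Bc in 1 of the 6 fits, and of the 5 only Hsp83 passed in all 6.

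Markers of enterocytes, the absorptive cells that secrete digestive enzymes, were higher as a list. Of 43 markers 24 were tested, 2 rose, 0 fell and 22 did not pass, with a median log2 fold change of 0.85; adjusted over the list alone, 7 were higher. Of the 24 tested markers, 12 belong to the Jonah protease family. The 2 were Jon25Biii and the amylase gene Amy-p (71.1 ± 15.5 to 170 ± 55.9 CPM, log2 fold change 1.26, SE 0.25; SD, n = 3 each). The brush border gene mex1 was at 137 ± 24.8 against 123 ± 27.5 CPM and Myo31DF at 16.8 ± 6.84 against 17.1 ± 1.55 CPM. The camera adjusted p was 0.000183 (Benjamini-Hochberg); it was 0.395 with an estimated correlation and 0.259 with fry. Without control replicate 1 the camera adjusted p was 0.0516 and the median log2 fold change 0.30. The median was 1.87 without control replicate 2 and 0.48 without the replicate labelled Pex5-depleted 1. Jon25Biii and Amy-p lost their calls in 2 and 4 of the edgeR fits without 1 library, with adjusted p up to 0.0637 and 0.138.

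**Figure D3:**
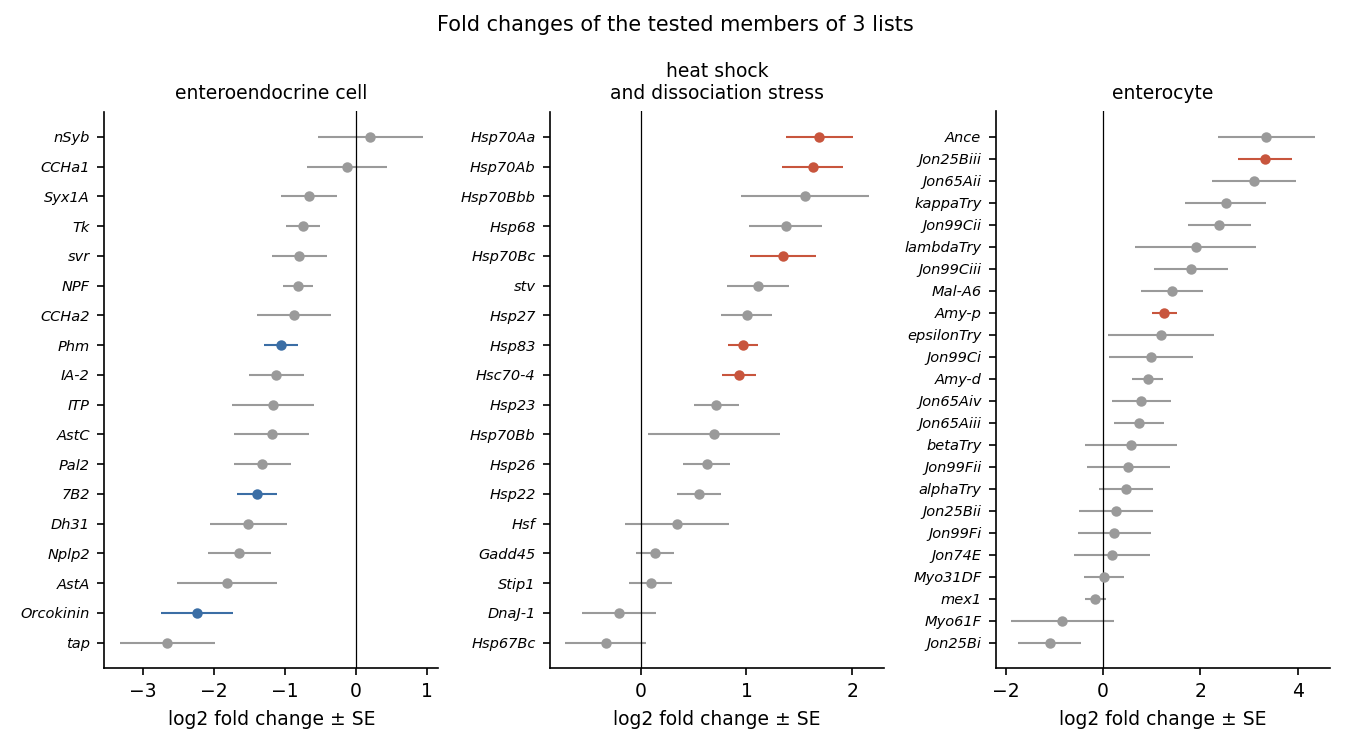
Log2 fold changes (horizontal axes, points) with their standard errors (bars) for the tested enteroendocrine, heat shock and enterocyte genes, libraries labelled Pex5-depleted over control; coloured points passed an adjusted p of 0.05 and grey points did not. Of the enteroendocrine genes 17 of 18 lie below 0, of the heat shock genes 16 of 18 lie above 0, and of the enterocyte genes 21 of 24 lie above 0.

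The progenitor markers themselves did not pass as a list (17 of 21 tested, 0 past the threshold, median log2 fold change 0.14, or 0.10 to 0.21 in the fits without 1 library, camera adjusted p 0.356 by Benjamini-Hochberg). The smallest p was that of mira, which encodes an adaptor of asymmetric stem cell division, at 14.3 ± 7.75 against 45.4 ± 18.3 CPM (log2 fold change 1.67, SE 0.44, adjusted p = 0.0788 by edgeR, Benjamini-Hochberg). It passed with DESeq2 (adjusted p = 0.00724), without a count filter (0.00138) and without control replicate 2 (0.0471). It did not pass in the other 5 fits without 1 library (adjusted p up to 0.268 by edgeR, log2 fold change as low as 1.28), nor with limma-voom (0.0630) or the length offset (0.106). Visceral muscle had 5 tested markers of 28, with 0 past the threshold, a median between -0.563 and 0.261 in the fits without 1 library and a camera adjusted p of 0.948 (Benjamini-Hochberg); its lowest p was that of Tm1, with a log2 fold change of -0.67 (SE 0.24). Haemocyte, fat body, and trachea and neuron markers had 1, 1 and 3 tested members, none past the threshold by edgeR, and testis and ovary markers had 0. The best of them, crq, Ilp6 and elav, had log2 fold changes of -0.11 (SE 0.39), 0.09 (SE 0.87) and 0.93 (SE 0.63), and in the fits without 1 library they lay between -0.26 and 0.06, -1.06 and 0.60, and 0.56 and 1.36.

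Lists closest to the design did not pass with all 6 libraries under the main settings. Of the peroxisome biogenesis genes 13 of 18 were tested and 0 passed (median log2 fold change -0.12, camera adjusted p 0.945 by Benjamini-Hochberg); the mean of the members, 0.22, had the opposite sign, and the median lay between -0.279 and 0.087 in the fits without 1 library. Pex14, the membrane docking partner of Pex5, had the smallest p of the list, at 96.7 ± 11.5 against 51.7 ± 6.46 CPM (log2 fold change -0.91, SE 0.22), with an adjusted p of 0.0523 by edgeR (Benjamini-Hochberg); adjusted over the list alone it was the 1 lower gene. Pex14 passed with DESeq2 (adjusted p = 0.00320), RLE factors (0.0459), no composition factor (0.0436), no count filter (0.0163) and limma-voom (0.0467). It passed in none of the 6 edgeR fits without 1 library (adjusted p 0.0853 to 0.193), nor with the filter of 10 UMIs in 3 libraries or the length offset. Pex13 had a log2 fold change of 1.51 (SE 0.71), with 12, 9 and 6 control UMIs. Of the peroxisomal enzymes 8 of 17 were tested, with a median of 0.53 and a camera adjusted p of 0.154, and the acyl-CoA oxidase gene CG17544 had a log2 fold change of 0.87 (SE 0.29). That list passed with the filter of 10 UMIs in 3 libraries (median 0.69, adjusted p 0.0434) and without control replicate 2 (0.76, 0.0165), but not with an estimated correlation (0.552) or fry (0.259). Its median was 0.33 without control replicate 3 and 0.39 without the replicate labelled Pex5-depleted 1 (camera adjusted p 0.295 and 0.509). Ether lipid and phosphatidylethanolamine synthesis had 8 of 18 genes tested, a median of 0.33 and a camera adjusted p of 0.607, and without the replicate labelled Pex5-depleted 1 the median was 0.14. CG5991 had a log2 fold change of -1.20 (SE 0.72), between -1.50 and -0.60 in the fits without 1 library. The list of fatty acid and sterol-regulated lipid synthesis had 13 of 16 fold changes positive, a median of 0.35 and a camera adjusted p of 0.0602, with CG3209 at 0.81 (SE 0.24). It passed without the replicate labelled Pex5-depleted 3 (0.0287), but not with an estimated correlation (0.395) or fry (0.134). CG3209 passed with DESeq2 (adjusted p = 0.0397) and in no edgeR fit without 1 library (0.196 to 0.332). Endoplasmic reticulum folding genes had a median of 0.14 over 14 tested genes (-0.015 without the replicate labelled Pex5-depleted 1, 0.27 without 3) and a camera adjusted p of 0.945; the protein disulfide isomerase gene CaBP1 had a log2 fold change of 0.52 (SE 0.19). Genes of the unfolded protein response and of degradation from the endoplasmic reticulum had a median of -0.16 over 23 tested genes (-0.08 without control replicate 1, -0.25 without control replicate 2) and a camera adjusted p of 0.356, with Manf at -0.73 (SE 0.23), which passed with DESeq2 (adjusted p = 0.0397) and in no edgeR fit without 1 library (0.154 to 0.405). No member of the last 5 lists passed edgeR's threshold (Benjamini-Hochberg) in the test of all 6 libraries.

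Of the immune deficiency pathway and antimicrobial peptide genes 8 of 26 were tested, PGRP-LB and AttD fell and 6 did not pass; adjusted over the list alone, 3 were lower, with pirk as the third. The list's camera adjusted p was 0.0543 (Benjamini-Hochberg) with a median log2 fold change of -0.41. The list passed with the filter of 10 UMIs in 3 libraries (adjusted p 0.0434) and with the length offset, added after the data were seen (0.0408). It also passed without the replicates labelled Pex5-depleted 1 (median -0.74, adjusted p 0.0333) or 3 (median -0.50, adjusted p 0.0287). Without the replicate labelled Pex5-depleted 2 its median was -0.21 (adjusted p 0.235), and without a count filter the median turned to 0.62 (0.944). It did not pass with an estimated correlation (0.395) or with fry (0.0984). In the oxidative stress list the thioredoxin gene Trx-2 fell (log2 fold change -1.16, SE 0.27), 28 of 29 did not pass, and the camera adjusted p was 0.793; adjusted over the list alone, 3 were higher and 4 lower. In the respiratory chain list SdhB, a subunit of succinate dehydrogenase, rose from 53.3 ± 12.7 to 139 ± 25.7 CPM (1.38, SE 0.24; SD, n = 3 each), 65 of 66 did not pass, and the camera adjusted p was 0.631. SdhB lost its call without the replicate labelled Pex5-depleted 3 (adjusted p 0.0614 by edgeR, Benjamini-Hochberg). AttD passed in 0 and Trx-2 in 1 of the 6 edgeR fits without 1 library, with adjusted p up to 0.193 and 0.225. Trx-2 lost its call also with limma-voom (0.0539) and with the length offset (0.0577).

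With all 6 libraries, the remaining lists had no gene past edgeR's threshold (Benjamini-Hochberg) and no call by camera. Apoptosis genes had a median log2 fold change of 0.50 and a camera adjusted p of 0.0602; fry, which asks whether the members move on balance 1 way, gave an adjusted p of 0.0349, where camera with an estimated correlation gave 0.395. Camera called the list in none of the fits without 1 library, and without the replicate labelled Pex5-depleted 3 the median was 0.25 (adjusted p 0.198). The initiator caspase gene Dredd had a log2 fold change of 2.14 (SE 0.88), with 2, 1 and 17 UMIs in the controls and 13, 31 and 40 in the other group, and the fits without 1 library gave 1.57 to 4.09. Genes of the JAK-STAT, EGFR and JNK pathways had a median of 0.34 and a camera adjusted p of 0.154, with the EGFR ligand gene spi at -0.70 (SE 0.28); the list passed without the replicate labelled Pex5-depleted 3 (0.0287), but not with an estimated correlation (0.754) or fry (0.532). Cell cycle genes had a median of 0.08 over 26 tested genes with a downward camera direction (adjusted p 0.948), and RnrS, a ribonucleotide reductase subunit gene, was at -0.83 (SE 0.33), which shrank to -0.28 without control replicate 3, at 104 CPM against 42.6 and 44.0 in the other controls. Autophagy and TOR genes had a median of 0.08, also with a downward camera direction (adjusted p 0.945), and Lamp1 was at -0.66 (SE 0.22). Cytosolic ribosomal protein genes had a median of 0.01 over 84 tested genes, a downward camera direction (adjusted p 0.872) and RpL34a at -0.52 (SE 0.15), which passed with DESeq2 (adjusted p = 0.00629), no composition factor (0.0394) and no count filter (0.0421), but in no edgeR fit without 1 library (0.154 to 0.274). In the fits without 1 library the medians of the cell cycle, autophagy and ribosomal protein lists lay between -0.125 and 0.183, 0.002 and 0.124, and -0.119 and 0.113.

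The authors' deposited table of fold changes gives 13635 genes a fold, of which 11716 (85.9%) have a false discovery rate under 0.05, 7467 positive and 4249 negative. It does not name the sides of its comparison. In the authors' deposited table Pex5 has a fold of -2.50 (false discovery rate 9.27e-06) and ERp60 a fold of -4.09 (6.08e-58). Across 1581 genes with a mean log2 CPM above 5, the folds of the authors' deposited table and those from the UMI counts had a Spearman rho of 0.084, and genes are not independent replicates. Of 89 genes past the threshold in the counts that are in the authors' deposited table, 48 have the same sign in both. Of those 48, 5 are positive in both and the rest negative in both. The LysD fold is -15.3 in the authors' deposited table, where the counts gave 104 against 5.25 CPM. Of genes under 1 CPM in the 6 libraries 92.4% have a positive fold in the authors' deposited table, and of genes over 1000 CPM 4.8% have.

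**Figure D4:**
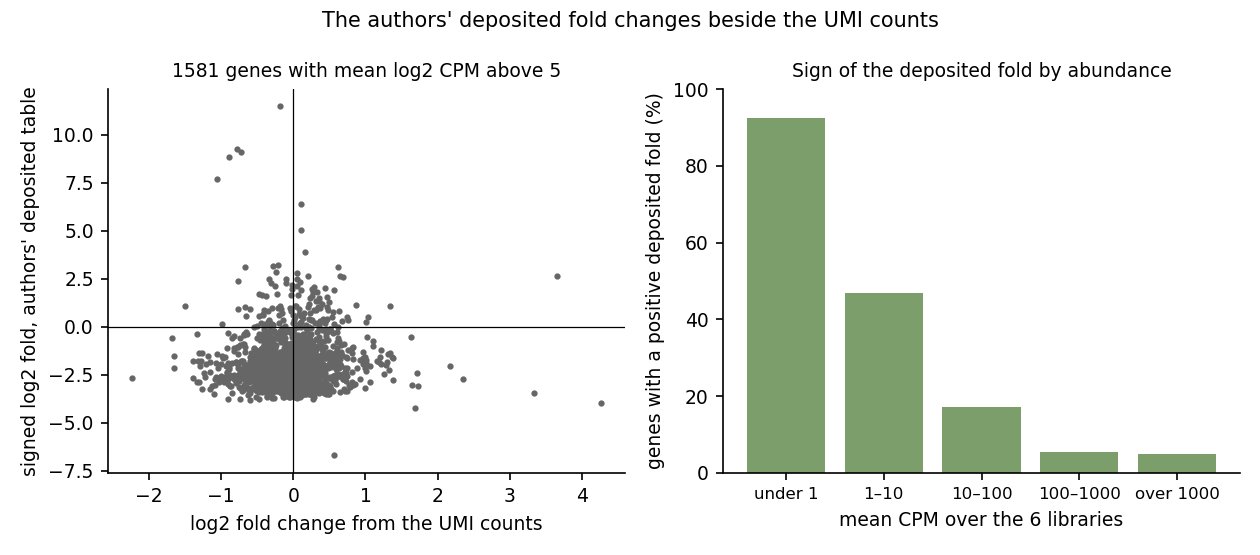
Left, the signed log2 fold of the authors' deposited table (vertical axis) against the log2 fold change from the UMI counts (horizontal axis), 1 point for each of 1581 genes; right, the percentage of genes with a positive fold in the authors' deposited table (bars) by mean CPM over the 6 libraries. The points show a Spearman rho of 0.084, and the bars go from 92.4% under 1 CPM to 4.8% over 1000 CPM.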

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

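The length offset was chosen after seeing the data; the other settings were planned. With all 93 calls as the reference, RLE factors shared 91 calls, no composition factor 85, no count filter 91, the filter of 10 UMIs in 3 libraries 92, the length offset 71, DESeq2 85 and limma-voom 71, all with the same sign. No setting moved the median of all genes by more than 0.064 on the log2 scale. Without a composition factor 41% of the calls were higher, against 50.5%. Without a count filter, which tests 13189 genes, 88 genes were higher and 109 lower. DESeq2 called 88 higher and 120 lower, and the cause was not tested. Its default filters for low means and outlying counts were on, and 2078 genes had no adjusted p. The filter of 10 UMIs in 3 libraries tested 5717 genes, more than the main filter, and called 5 lists, adding peroxisomal enzymes and the immune deficiency list. With an estimated correlation 0 lists passed, and with fry 1 did (apoptosis). These tests allow for more correlation between genes or ask another question. Pex5 passed in no setting that gave it an adjusted p (lowest 0.395, by edgeR in a fit without 1 library). DESeq2 is not among those settings, since it gave no adjusted p to compare for Pex5.

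In fits without 1 library, which hold fewer samples, 12 to 47 genes were higher, 5 to 33 lower, and 2 to 6 lists passed. The log2 fold of Pex5 lay between -0.029 and 1.757, and that of ERp60 between -0.075 and 0.112; crq lay between -0.258 and 0.057 and Ilp6 between -1.063 and 0.599. Medians of lists that never passed and whose direction turned were -0.279 to 0.087 for peroxisome biogenesis, -0.015 to 0.274 for endoplasmic reticulum folding, -0.125 to 0.183 for cell cycle, 0.002 to 0.124 for autophagy, -0.119 to 0.113 for ribosomal proteins and -0.563 to 0.261 for visceral muscle.

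The counts gave no sign that the replicate numbers pair the samples. In their deviations from the group means, same-numbered libraries had correlations of -0.027, -0.026 and -0.057. No sample correlated best with its own number. Within such small groups these deviations cancel for each gene, so the check cannot exclude that same-numbered libraries were handled together. With the replicate block, which costs residual degrees of freedom, 58 genes were called, 23 of them lower, 51 shared. Under the block camera turned for autophagy (median 0.047) and visceral muscle (-0.076).

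The ERp60 fold turned negative with RLE factors (-0.007), no composition factor (-0.053), no count filter (-0.056), the length offset (-0.051) and DESeq2 (-0.007), each within its standard error. The camera direction turned without a count filter for peroxisome biogenesis (median -0.142), cell cycle (0.031) and visceral muscle (-0.146). It turned with the length offset for endoplasmic reticulum folding (0.065), oxidative stress (-0.092), ribosomal proteins (0.075), the respiratory chain (0.004) and visceral muscle (0.015). The direction under fry differed for peroxisome biogenesis (-0.118), cell cycle (0.079) and autophagy (0.082). The cause was not tested. Of comparisons of a called named gene with an alternative, 330 kept the call and 129 lost it with the direction kept. Genes without an adjusted p with DESeq2 were left out of these counts. For called lists 35 kept and 7 lost it. Depth was not separated from the spread between replicates.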

Other observations

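Gene families were grouped by symbol after the data were seen, and 15 were looked at. Transcripts of the mitochondrial genome were positive in 25 of 26 genes (median log2 fold change 0.45, camera adjusted p 6.98e-05, Benjamini-Hochberg). With an estimated correlation that adjusted p was 0.523. The 1 gene past edgeR's threshold was mt:tRNA:Leu-TAG (log2 fold change 0.635, adjusted p 0.0479), which passed in 1 of the 6 fits without 1 library. The ribosomal RNA mt:lrRNA, at 0.56 (SE 0.15), did not pass (adjusted p 0.0838 by edgeR). Both entries are on the minus strand and adjoin, mt:tRNA:Leu-TAG at 12670 to 12734 and mt:lrRNA at 12734 to 14058. Whether their counts are separate was not tested. Proteins that import nuclear-encoded products into mitochondria (Tim and Tom) went the other way, with 0 of 10 positive and a median of -0.36 (camera adjusted p 0.0054). Of these Tim10 fell by 0.76 (SE 0.17), with an adjusted p of 0.0388 by edgeR's quasi-likelihood test, and it passed in 1 of the 6 fits without 1 library. Transfer RNA synthetase genes were positive in 22 of 29 (median 0.22, camera adjusted p 0.0054), and Jonah protease genes in 11 of 12 (median 0.76, camera adjusted p 0.0054). These 12 Jonah genes are also members of the fixed enterocyte list, so they are not a separate observation. Tetraspanin genes were positive in 6 of 18 (median -0.23, camera adjusted p 0.0188). Lysozyme genes had 4 of 5 risen, while LysX was at -0.41 (SE 0.78). With an estimated correlation no family passed, and the lowest adjusted p was 0.135.

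The eye pigment transporter gene white (w), often carried as a marker on transgenes, rose by 1.11 on the log2 scale (SE 0.18, adjusted p = 0.00616 by edgeR, Benjamini-Hochberg); it was chosen after its value was seen, and it passed in 5 of the 6 fits without 1 library. Yolk protein genes, markers of fat body and ovarian follicle cells, were near absent except in the replicate labelled Pex5-depleted 2, where Yp1, Yp2 and Yp3 had 65, 37 and 135 UMIs. The highest in any other library were 7, 1 and 3.

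The tests of Pex5, of the deposited table and of the enteroendocrine medians without 1 library below were chosen only after their results were seen, and the other tests were written before. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 47 higher and 46 lower genes by edgeR, and each of the others gave 0 in either direction, so 1 of 10 splits reached each count. For gene lists by camera with the preset correlation, 4 of 10 splits gave at least 3, and the highest of the others gave 4. The enteroendocrine list had its smallest p in the real split, where 3 other splits also called it (lowest adjusted p 3.67e-05). The enterocyte list passed in 3 other splits with an adjusted p as low as 4.05e-08, below that of the real split, and the heat shock list in 4 (lowest 1.37e-05).

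The Pex5 transcript was not lower in the libraries labelled Pex5-depleted. A single control library under that label is argued against by the first principal component, on which the groups lay 35.3 apart. The range was 10.1 among the controls and 25.3 among the libraries labelled Pex5-depleted. All labels exchanged between the groups would leave that gap as it is and stay open, since the 95% interval of the Pex5 log2 fold change, -0.62 to 3.11, spans 0 with all 6 libraries and lies above 0 (lower bound 0.10) in only 1 of the 6 fits without 1 library, that without the replicate labelled Pex5-depleted 1. A 2-fold fall hidden by the low count also stays open, since the lower bound of that interval was -2.38 without the replicate labelled Pex5-depleted 3, -1.11 without control replicate 1 and -1.01 without control replicate 2, though -0.73 or higher in the other 3 fits. With 2 to 41 UMIs and 0.726 to 14.01 CPM in the libraries under that label, a fall and a rise cannot be told apart, and a depletion acting on the protein, or cut transcripts still captured at their 3' end, may also leave the count high, both untested.

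Enteroendocrine genes were lower in the libraries labelled Pex5-depleted by camera with its preset correlation, but the list was not called with an estimated correlation (adjusted p = 0.395) or with fry (adjusted p = 0.0984). A trend with transcript length and a single deciding library are argued against, since the median was -1.11 with the length offset and -0.98 to -1.46 in the fits without 1 library; the planned test by the camera adjusted p (highest 9.83e-07) decides little, as that p passed in other splits too. A lower share of RNA from all enteroendocrine classes alike predicts equal folds of the peptide hormone genes within their errors. The 10 tested were all lower, from -0.124 to -2.24 on the log2 scale, with a weighted mean of -1.01 (SE 0.12, 2.01-fold). Their scatter did not pass 0.05 (p = 0.0916, Cochran's Q over n = 10 genes, taken as independent). The list had an estimated correlation between genes of 0.193, which that SE and p leave out. A p above 0.05 does not show equal folds, so this explanation was not refuted and stays open. The sort on esg-driven GFP should remove mature enteroendocrine cells, yet Orcokinin and NPF stood at 1278 and 545 CPM in the controls, and 1 tested marker, nSyb, is also on the neuron list. Sort purity, fewer such cells in the gut and a change inside progenitors stay open as hypotheses, untested here.

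The folds of the authors' deposited table did not follow the UMI counts. That it describes the same comparison is argued against by a Spearman rho of 0.084 across 1581 genes. That it compares the sorted cells with other material is consistent with a rho of -0.783 between its folds and mean abundance over 11092 genes, where low genes weigh heavily; over the 5424 tested genes the rho was -0.467, and that of the folds of the counts -0.133, while over the 1581 genes above a log2 CPM of 5 they were -0.201 and -0.038, so the trend is weak among abundant genes. Of 2543 genes in the authors' deposited table with no UMI in these 6 libraries, 96.7% have a positive fold, with a median of 260-fold. Which samples entered it stays open.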
